A study of Mus musculus with 2 samples.

How the data were processed

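MicroRNAs (miRNAs) were measured by sequencing small RNA libraries, with a size range under 30 in the labels, from total RNA of the adrenal gland of 18 to 20 month old female mice. The animals were B6CASTF1/J, first-generation hybrids of C57BL/6J and CAST/EiJ parents. The labels give 1 group of 2 biological replicates. Each replicate is a distinct tissue sample, but both are entered under the same donor record, so the spread between them is the spread between these samples. No second age, sex, tissue or strain was analysed here, and no comparison between conditions was made.

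The deposited tables hold raw counts of reads per miRNA gene, in 3 columns: strand ignored, own strand of the gene and opposite strand. The genome build was mm10 and the annotation GENCODE release M21, per the deposited notes that accompany the tables. That build is of C57BL/6J, so reads that differ from it at CAST/EiJ alleles may be missing from the gene counts, which was not tested here. The aligner, the counting program and the adapter trimming are not given in the sources used here. All 2202 gene identifiers matched GENCODE M21, from which symbols, positions (1-based) and host genes were taken. Where several genes on the same strand contained a miRNA, a single host was named, protein-coding genes first and then by symbol order. Other host genes can therefore exist at a named position. Counts belong to a hairpin gene, so the arms of a hairpin were not resolved. The meaning of the strand columns was read from the values, and the stranded column with the larger total in both libraries was taken as own strand.

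The first 4 rows of each table count reads that name no gene, and they were left out of library sizes and tests. Of the 9807567 reads in the replicate 1 table, 40.6% were unmapped, 24.0% aligned to several places, 8.94% fell in no miRNA gene and 26.4% were counted on the own strand of a gene. Of the 6993665 reads of replicate 2, the shares were 29.8%, 28.0%, 9.44% and 32.8%. Reads that align to several places are not in the gene counts, so a miRNA whose mature sequence is encoded at several loci can be undercounted. Genes that share 18 bases of their annotated hairpin with a non-overlapping miRNA gene numbered 1120. A gene overlapped by a miRNA gene on the opposite strand loses its reads when strand is ignored, and 64 genes were of this kind.

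Own-strand counts totalled 2590051 in replicate 1 and 2291030 in replicate 2. CPM are counts per 1000000 of these totals, and percentages of counts refer to them as well. Wilson 95% intervals were computed for shares in single libraries (those of the read classes above were at most 0.0696 percentage points wide), and a count of 0 allows up to 3 counts, which is 1.16 CPM in replicate 1 and 1.31 CPM in replicate 2. Intervals and this limit cover counting error only, since PCR copies are not independent molecules. A miRNA was called detected with at least 10 counts in each library.

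Reads of the 2 libraries were compared per miRNA with a two-sided exact conditional binomial test on raw counts. Library sizes were scaled with edgeR's TMM factors, 1.01 and 0.987, and p values were adjusted by Benjamini-Hochberg over miRNAs with a summed count of at least 20. This test compares these 2 libraries, with counting error only. Log2 ratios are replicate 2 over replicate 1 with a prior count of 0.5, and their 95% intervals are exact conditional ones. The biological coefficient of variation came from edgeR's common dispersion with an intercept-only design. Pearson and Spearman correlations used log2(CPM + 1).

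The 21 miRNA lists (cell types, organs, families and clusters) and the tests and thresholds of the comparisons were fixed before the data were examined, except where a test is said to have been chosen later. For each list, CPM were summed over its measured members. The median level of a list, over its detected members only, was placed among 10000 random lists of the same size drawn from the detected miRNAs. The median log2 ratio, over members with a summed count of at least 20, was placed among 10000 random lists matched on decile of mean level. This was done for lists with at least 3 such members. Of the listed symbols, 7 had no match in the annotation. Adjacent detected miRNA genes on the same strand within 10 kb were taken as neighbours, their levels were compared by Spearman correlation with 10000 permutations of partners, one-sided, and chains of neighbours were called clusters. The permutation test of hairpin base composition, with 100000 permutations, and the exact permutation tests within the let-7 family were two-sided, and the shuffling of directions within clusters was one-sided.

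Genes were named by a fixed rule: the 12 with the highest mean CPM; the 3 members of each list with the highest mean CPM (2 in lists under 5 measured members) among those with at least 10 counts in a library; and the 5 with the largest log2 ratio in each direction among those with a mean count of at least 100 that passed the test. Other genes are said to have been chosen after their values were seen.

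The exact test was tried on counts simulated with counting noise only. Over 368 tested genes it found 74.2% of the genes changed 1.5-fold, 87.9% of those changed 2-fold and 100% of those changed 4-fold. It called 0 of 367 genes when no change was simulated. These rates do not describe libraries with a spread beyond counting noise, such as the coefficient of variation of 0.431 found here. For coefficients of variation simulated at 0.2 and 0.4, edgeR returned 0.195 and 0.397, and DESeq2's median gene-wise dispersion returned 0.0956 and 0.259. Of 20 simulated lists of 10 members shifted by 1 on the log2 scale, 19 lay outside the central 95% of random lists, as did 2 of 20 unshifted lists.

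Alternatives were other detection minimums, the strand-ignored column, leaving out either replicate, DESeq2 size factors or total counts in place of TMM, no filter on low counts, other pseudocounts and prior counts, a minimum summed count of 200, and neighbour distances of 2 kb and 50 kb. Leaving out genes that share 18 bases, and asking for a fold difference of 2 as well, were alternatives chosen after seeing the data. Software was R 4.3.3 with edgeR 4.0.16 and DESeq2 1.42.0, and Python 3.11.15 with SciPy 1.17.1, NumPy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.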

Results

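Small RNA libraries from the adrenal gland of aged female mice were profiled in 1 group of 2 biological replicates. The own-strand counts assigned to miRNA genes numbered 2590051 in replicate 1 and 2291030 in replicate 2. With a single group, the data describe the miRNA profile of the tissue and the difference between its 2 libraries.

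Among reads counted in a gene, the adrenal profile was dominated by let-7 family members and by a small set of other miRNAs. Reads that align to several places, 0.910 and 0.855 for each counted read in replicates 1 and 2, are left out. The ranks and shares below can therefore understate miRNAs encoded at several loci. Mirlet7b was the most abundant gene, at 12.02% ± 2.34 of counts (SD, n = 2), followed by Mirlet7g at 7.63% ± 0.596 (SD, n = 2). Mir375, known from pancreatic islets and other endocrine cells, took 5.82% ± 0.594 (SD, n = 2) and Mir378a, encoded in Ppargc1b, took 5.22% ± 0.885 (SD, n = 2). Mir139 took 5.11% ± 0.306 (SD, n = 2) and the endothelial Mir126a took 4.91% ± 2.22 (SD, n = 2). Mir23b held 3.86% ± 1.89, Mir23a 3.72% ± 1.98, Mir10a 3.39% ± 0.403, Mirlet7i 3.26% ± 0.220, Mirlet7d 3.24% ± 1.08 and Mir21a 2.86% ± 1.00 (SD, n = 2 each). The 10 most abundant miRNAs together held 53.7% of counts in replicate 1 (Wilson 95% interval 53.6 to 53.7) and 56.2% in replicate 2 (56.1 to 56.3), a mean of 54.9% ± 1.79 (SD, n = 2). At least 10 counts were found in both libraries for 339 of the 2202 annotated miRNA genes.

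Positions are given on mm10 with GENCODE M21. Mirlet7b (ENSMUSG00000065564.1) lies on chromosome 15, 85707319 to 85707403, in an exon of the noncoding gene Lncppara. Mirlet7g (ENSMUSG00000065440.1) lies on chromosome 9, 106178840 to 106178927, in an intron of Wdr82. Mir375 (ENSMUSG00000065616.3) is intergenic on chromosome 1, 74900658 to 74900721. Mir378a (ENSMUSG00000105200.1) lies on chromosome 18, 61397835 to 61397900, in an intron of Ppargc1b. Mir139 (ENSMUSG00000065446.1) lies on chromosome 7, 101475376 to 101475443, in an intron of Gm45837. Mir126a (ENSMUSG00000065540.1) lies on chromosome 2, 26591357 to 26591429, overlapping an exon of Egfl7. Mir23b (ENSMUSG00000065599.2) lies on chromosome 13, 63300484 to 63300557, in an intron of 2010111I01Rik, and Mir23a (ENSMUSG00000065611.1) is intergenic on chromosome 8, 84208518 to 84208592. Mir378a and Mir126a are overlapped by a miRNA gene on the opposite strand, and with strand ignored their levels were 0 and 0.947 CPM.

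**Figure D1:**
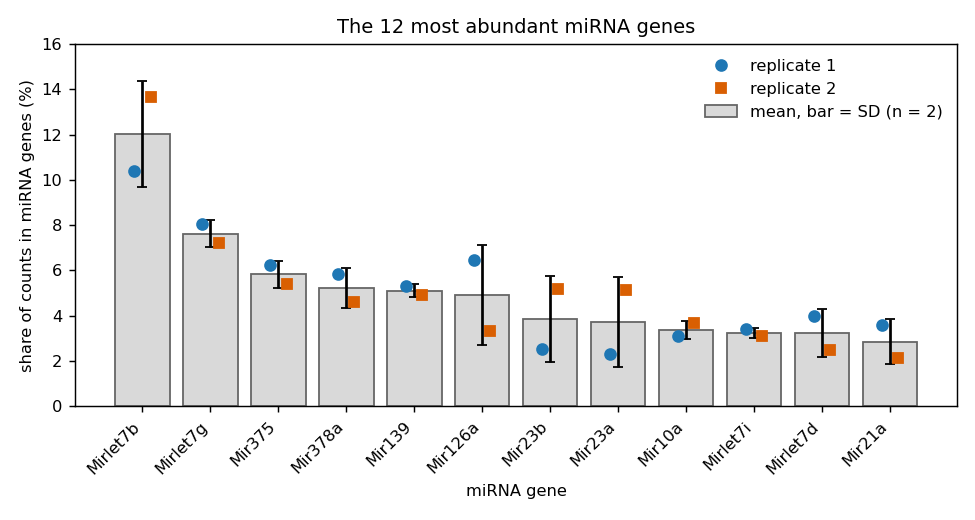
Share of the counts in miRNA genes (vertical axis, percent) for the 12 most abundant miRNA genes (horizontal axis). Grey bars are means with SD (n = 2), circles are replicate 1 and squares are replicate 2; Mirlet7b stands highest at 12.02% and Mir21a closes the series at 2.86%.

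The let-7 family, whose members are abundant in differentiated tissues, was the largest of the fixed lists, with 28.5% ± 0.207 of counts (SD, n = 2) over 12 members. Mesenchymal and smooth muscle miRNAs held 7.99% ± 0.142 (SD, n = 2), led by Mir10a, by Mir143 at 2.23% ± 0.678 and by Mir10b at 2.01% ± 0.486. Neuronal and neuroendocrine miRNAs, listed for the adrenal medulla, held 6.21% ± 0.680 (SD, n = 2), nearly all of it Mir375, with Mir7b at 0.284% ± 0.0708 and Mir137 at 0.0439% ± 0.00562. Of the 20 measured members of this list, 16 share 18 bases with another miRNA gene. Their reads can be lost among those that align to several places, so their levels can be too low. The endothelial list held 4.91% ± 2.22 (SD, n = 2), from Mir126a. Hormone-responsive adrenal miRNAs, described as regulators of steroid hormone production, held 4.20% ± 1.43 (SD, n = 2), with Mir21a, Mir125a at 0.734% ± 0.0765 and Mir214 at 0.159% ± 0.168. The median level of a list's detected members was set against random lists of detected miRNAs. It lay at percentile 99.97 for the let-7 list (12 of 12 measured members detected) and 99.87 for the mesenchymal list (6 of 9). The ageing list (11 of 11) lay at 99.035, the neuronal list (13 of 20) at 16.7 and the hormone-responsive list (14 of 15) at 84.5.

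Lists for other tissues and cell types ranged from over 5% of counts to almost none. The adipose-enriched list held 5.53% ± 0.822 (SD, n = 2), from Mir378a with Mir335 and Mir193a behind it, and the kidney-enriched list held 4.13% ± 0.323 (SD, n = 2), from Mir10a and from Mir30a at 0.718% ± 0.0768. Leukocyte miRNAs summed to 3037 ± 61.4 CPM (SD, n = 2), with Mir146 at 991.2 ± 28.9, Mir342 at 638 ± 8.50 and Mir150 at 528 ± 9.33 CPM. Epithelial miRNAs summed to 1532 ± 480.4 CPM, of which Mir203 gave 1383 ± 332 CPM (SD, n = 2 each). The erythroid list reached 701 ± 291 CPM, led by Mir451a at 544 ± 276 CPM, and the liver miRNA Mir122 reached 662 ± 56.5 CPM (SD, n = 2 each). The striated muscle list reached 339 ± 365 CPM and the ovary and gonad list 227 ± 25.5 CPM, with Mir383 at 205 ± 22.2 and Mir202 at 20.3 ± 4.62 CPM (SD, n = 2 each). Pancreatic acinar miRNAs summed to 1.93 CPM in replicate 1 and had no counts in replicate 2, which allows up to 1.31 CPM.

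Among miRNAs grouped by locus, those of the imprinted Dlk1-Dio3 region on chromosome 12 held 5.79% ± 0.227 of counts (SD, n = 2), with 50 of 60 measured members detected. Mir127, at chromosome 12, 109592846 to 109592915, led the region at 2.10% ± 0.0911, followed by Mir379 at 0.532% ± 0.124 and Mir411 at 0.511% ± 0.0923 (SD, n = 2 each). Other imprinted-locus miRNAs summed to 3104 ± 23.7 CPM (SD, n = 2), although Mir298 was 1.85-fold higher in replicate 1 and Mir296, its neighbour on chromosome 2, was 1.79-fold higher in replicate 2. The ageing and senescence-associated list held 5.89% ± 1.84 (SD, n = 2), from Mir21a, Mir22 at 1.26% ± 0.472 and Mir29a at 0.996% ± 0.242. The X-linked Mir322 and Mir221 clusters held 1.17% ± 0.0315, with Mir322 at 0.731% ± 0.0485, and the Mir17 cluster with its paralogs held 0.613% ± 0.0329, with Mir93 at 0.217% ± 0.0208 (SD, n = 2 each). The list of mature sequences encoded at several loci held 1.14% ± 0.141 over 58 members (SD, n = 2). Reads of these sequences that align to several places are not counted, so this share is no measure of their abundance. The ribosomal RNA-like entry Mir6236 reached 137 ± 113 CPM (SD, n = 2). Of the 21 lists, 11 had a mean of at least 10000 CPM.

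**Figure D2:**
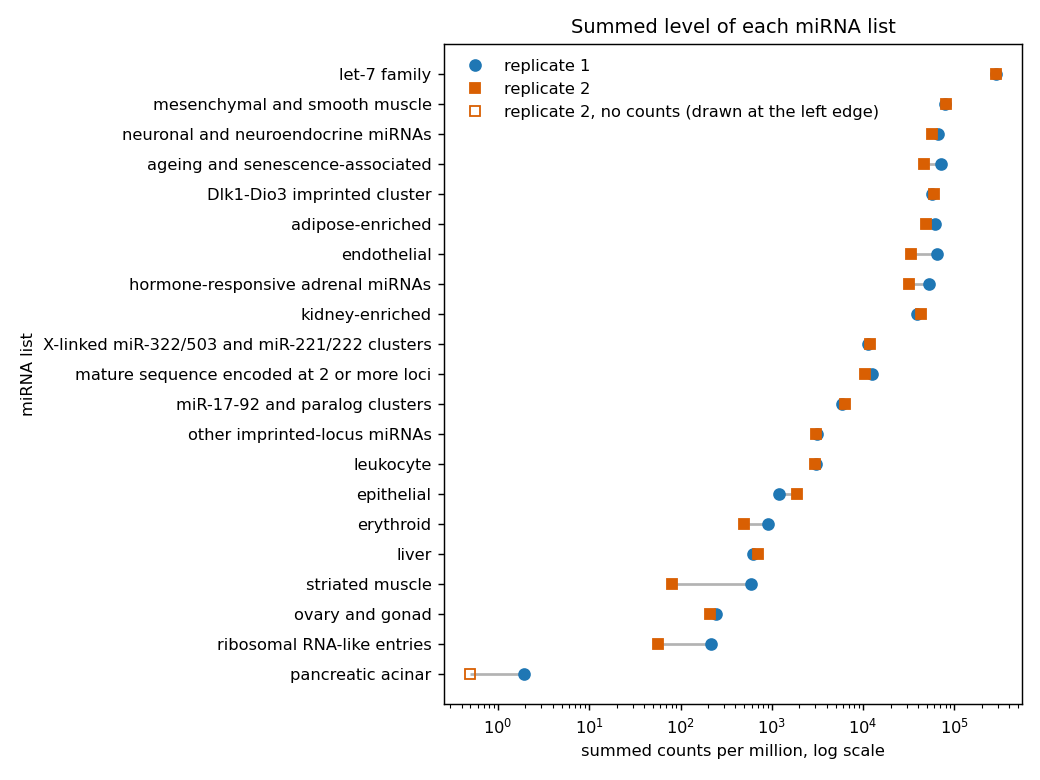
Summed level of each fixed miRNA list (rows) in CPM on a log axis, with a circle for replicate 1, a square for replicate 2 and a line joining them; an open square marks a library with no counts. The let-7 family lies highest, and the striated muscle list has the widest gap among lists with counts in both libraries, 598 against 81.2 CPM.

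Between the 2 libraries, replicate 1 carried more of the miRNAs encoded in cardiac and slow muscle myosin genes, and replicate 2 carried more of the Mir302 cluster and of the epithelial Mir200c. Mir208a, in an intron of Myh6 (chromosome 14, 54949060 to 54949142), had 231 counts in replicate 1 and 0 in replicate 2, at least 66.4-fold higher against a limit of 3 counts in that library, while the exact interval, which includes counting error in both libraries, reaches down to 53.5-fold. Mir499, in an intron of Myh7b (chromosome 2, 155622880 to 155622958), had 420 and 3 counts, a log2 ratio of -6.71 (95% interval -9.20 to -5.36). Mir302b, Mir302a and Mir302d, a cluster on chromosome 3 (127545228 to 127545689), had log2 ratios of 3.92, 3.54 and 2.97. Mir200c (chromosome 6, 124718322 to 124718390) had 65 counts in replicate 1 and 452 in replicate 2, a log2 ratio of 3.00 (2.63 to 3.41).

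The remaining genes with the largest ratios were Mir214, Mir152 and Mir6236, higher in replicate 1, and Mir1291, higher in replicate 2. Mir214, in an exon of Dnm3os on chromosome 1, had 7200 and 933 counts, a log2 ratio of -2.73 (-2.83 to -2.64). Mir152, in an intron of Copz2 on chromosome 11, had 901 and 164 counts, a log2 ratio of -2.24, and Mir6236 a log2 ratio of -1.88 (-2.17 to -1.61). Mir1291, in an intron of Kansl2 on chromosome 15, had a log2 ratio of 2.10 (1.85 to 2.37). Of the most abundant miRNAs, Mir126a was 1.89-fold higher in replicate 1, and Mir23a and Mir23b were 2.27-fold and 2.11-fold higher in replicate 2. Mir146, Mir342 and Mir150 had log2 ratios of -0.02 (-0.10 to 0.06), 0.01 (-0.09 to 0.11) and 0.00 (-0.11 to 0.11), with adjusted p of 0.678, 0.898 and 1.0 in the exact test; with DESeq2 size factors Mir146 passed it (log2 ratio -0.11, adjusted p 0.0108).

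Across the 367 miRNAs tested, 230 differed between the libraries in the exact conditional binomial test at an adjusted p of 0.05, 111 higher in replicate 2 and 119 higher in replicate 1. The median absolute log2 ratio was 0.46 and 298 of the 367 lay within 2-fold. The biological coefficient of variation was 0.431. Levels correlated across miRNAs with a Pearson r of 0.957 and a Spearman rho of 0.952, which are across genes, and genes are not independent replicates. The test has counting error as its only spread, so it does not separate a difference between these samples from one between library preparations. DESeq2's median gene-wise dispersion gave a coefficient of 0.201, and 65 miRNAs also differed by at least 2-fold, a limit chosen after seeing the data.

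**Figure D3:**
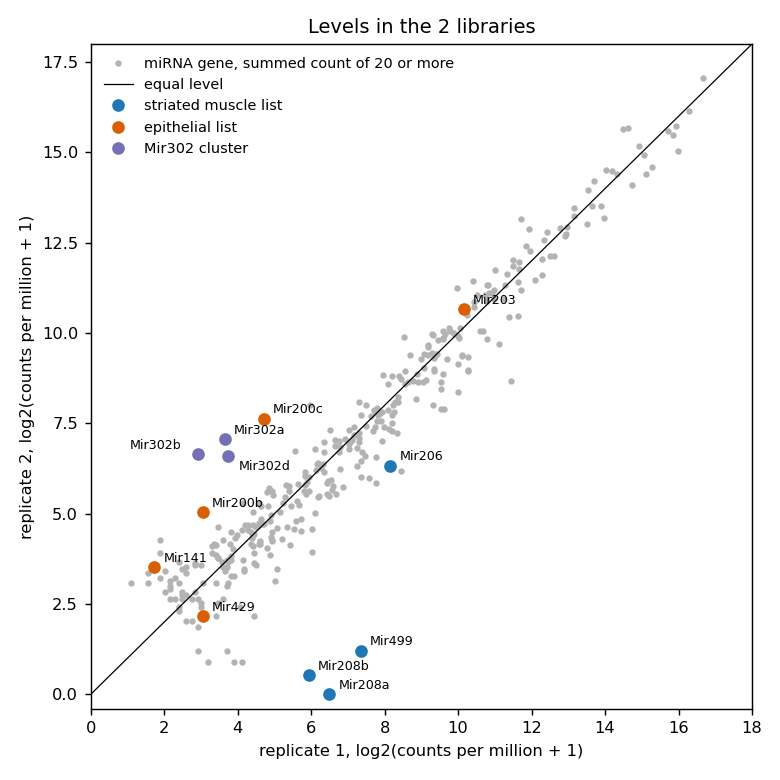
Level of each miRNA gene with a summed count of 20 or more in replicate 1 (horizontal axis) and replicate 2 (vertical axis), both as log2(CPM + 1), with a line of equal level. Members of the striated muscle list lie below the line, those of the Mir302 cluster above it, and in the epithelial list 4 of 5 tested members lie above it beyond counting error.

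Grouped by list, 4 of 4 tested striated muscle miRNAs were higher in replicate 1 and 4 of 5 tested epithelial miRNAs were higher in replicate 2. The muscle miRNAs were Mir206 with 737 and 182 counts, Mir208a, Mir499 and Mir208b, the last of these in an intron of Myh7 with 157 and 1 counts and named after its values were seen. The epithelial miRNAs were Mir200c, Mir200b with 19 and 73 counts, Mir203 with a log2 ratio of 0.53 and Mir141, named after its values were seen, with 6 and 24 counts. Mir429, also named after its values were seen, had 19 and 8 counts and did not pass (log2 ratio -0.99, adjusted p 0.169, exact test). Of 14 tested hormone-responsive adrenal miRNAs, 12 were higher in replicate 1 and 0 in replicate 2, among them Mir21a at a log2 ratio of -0.69 and Mir125a at -0.18. Of 11 ageing and senescence-associated miRNAs, 8 were higher in replicate 1 and 1 in replicate 2, among them Mir22 at -0.75 and Mir29a at -0.46. In the mesenchymal list 4 were higher in replicate 1 and 3 in replicate 2, with Mir143 at -0.59 and Mir10b at 0.54.

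The median log2 ratio was -6.62 for the striated muscle list (percentile 0.005 of matched random lists, and -6.29 with Mir208a at its bound) and 2.12 for the epithelial list (percentile 99.95). With a prior count of 5 in place of 0.5 these medians were -5.05 and 1.55, so their size depends on low counts. The median was -0.67 for the hormone-responsive list (percentile 0.33), -0.69 for the ageing list (0.185) and -0.59 for the mesenchymal list (2.02). These 5 of 16 lists lay outside the central 95%, where 0.8 would be expected if the members of a list varied independently. They need not, since the hormone-responsive list holds clustered genes such as Mir212 and Mir132, with log2 ratios from -1.44 to -1.37. The random lists draw genes singly, so 0.8 can be too low. Mir21a and Mir214 also each sit on a pair of these lists. With a minimum summed count of 200 the ageing list lay at percentile 4.36, the mesenchymal list at 66.8 and the Dlk1-Dio3 list at 97.7, and without genes that share 18 bases the first 2 of these lay at 4.54 and 59.8. The percentiles describe these libraries and test no condition.

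The other 11 lists lay inside the central 95%. In the let-7 family, 8 of 12 members were higher in replicate 1, and Mirlet7b and Mirlet7c-2 were higher in replicate 2 (percentile 25.3). Mirlet7c-2 did not pass with DESeq2 size factors (log2 ratio 0.04, adjusted p 0.290, exact test). The Dlk1-Dio3 region had 13 higher in replicate 1, 22 higher in replicate 2 and 15 that did not pass (percentile 96.4). The neuronal list had 6 higher in replicate 1 and 1 in replicate 2 of 13 tested (percentile 25.2), the leukocyte list 1 and 1 of 8 (52.3), the erythroid list 2 and 0 of 4 (32.8) and the kidney list 2 and 1 of 7 (35.0). The adipose list had 2 higher in replicate 1 and 3 in replicate 2 of 6 (percentile 74.9), the other imprinted miRNAs 1 and 2 of 5 (88.0), the Mir17 cluster and its paralogs 3 and 4 of 11 (47.5), the X-linked clusters 3 and 3 of 8 (63.4) and the mature sequences with several loci 17 and 9 of 41 (37.6). Among lists too short to be placed, both endothelial members, Mir126a and Mir126b, and Mir6236 were higher in replicate 1, Mir122 was higher in replicate 2, and neither of the 2 tested gonad miRNAs passed. Mir126b lies within Mir126a on the other strand, so by position its 31 and 3 counts are also the opposite-strand counts of Mir126a. They do not show whether it is a separate member. Mir383, 1 of the gonad miRNAs, had an adjusted p of 0.0718 in the exact test (log2 ratio -0.18), and passed with DESeq2 size factors (0.00514), total counts (0.0275) and strand ignored (0.0353). Adjusted over the list alone, the counts of differing miRNAs were equal to these except in the Dlk1-Dio3 region, with 36 against 35.

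Neighbouring miRNA genes had related levels, yet members of several clusters differed between the libraries in opposite directions. In the Mir23a cluster on chromosome 8 (84208518 to 84208921), Mir23a had a log2 ratio of 1.18, Mir27a of -0.69 and Mir24-2 of -0.88. In the Mir23b cluster on chromosome 13 (63300484 to 63301275), Mir23b had a ratio of 1.08 and Mir27b of -0.65, while Mir24-1 had 0.02 and did not pass (adjusted p 0.94955, exact test). At Spaca6 on chromosome 17 (17830188 to 17830879), Mir99b had a ratio of 1.46, while Mirlet7e had -0.09 and Mir125a -0.18. Mir145a had 1.07 and Mir143 -0.59 (chromosome 18, 61647825 to 61649258), and in Mcm7 on chromosome 5 Mir93 had 0.23, Mir106b -1.27 and Mir25 -1.17. Mir27a, Mir24-2, Mir27b, Mir24-1, Mir99b, Mirlet7e, Mir145a, Mir106b and Mir25 were chosen after their values were seen.

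Over 108 neighbouring pairs within 10 kb, the Spearman correlation of levels was 0.337 (permutation p = 2.0e-04, one-sided). The correlation was 0.423 within 2 kb and 0.307 within 50 kb. Without genes that share 18 bases it was 0.272 over 71 pairs (permutation p = 0.0123, one-sided). The pairs are not independent, since an inner gene of a cluster enters 2 of them. Clusters of 13 and 33 genes in the Dlk1-Dio3 region supply many of the pairs. The permutation treats pairs as independent, so its p value can be too small. The median absolute difference in log2 ratio was 0.51 within the 108 pairs and 0.64 in random pairs matched on level, at percentile 4.38 of the random medians. Of 43 clusters, 31 had at least 2 differing members, and 11 of these had members differing in both directions. This was fewer than the 19 (95% range 14 to 24) obtained by shuffling directions over the differing members of all clusters (permutation p = 0.00230, one-sided), a test chosen after the result was seen.

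**Figure D4:**
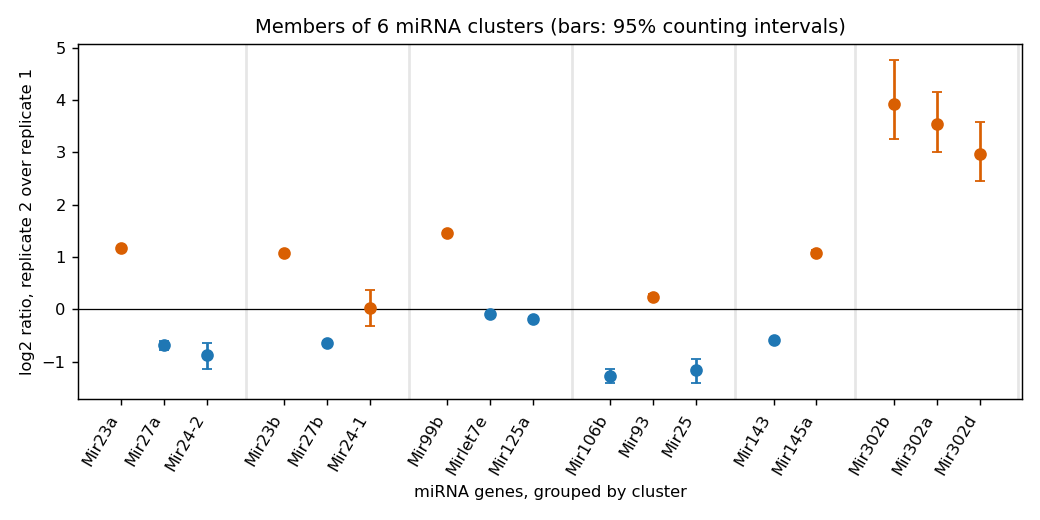
Log2 ratio of replicate 2 over replicate 1 (vertical axis) for the members of 6 miRNA clusters (horizontal axis), with 95% counting intervals; values above 0 are orange and values below 0 blue. In the first 5 clusters members lie on both sides of 0, while the 3 Mir302 genes lie between 2.97 and 3.92.

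Opposite-strand counts came almost entirely from the overlapping miRNA genes. They numbered 400130 in replicate 1 and 252273 in replicate 2. At genes with no miRNA gene on the opposite strand they numbered 396 and 191, against 2190320 and 2038951 own-strand counts. Ignoring strand made 399729 reads of replicate 1 and 252074 of replicate 2 ambiguous, among them those of Mir378a, Mir126a, Mir451a and Mir486.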

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

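In this part, both tests of let-7 levels were chosen after the result was seen.

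Reads were present in classes outside the gene counts. Reads aligned to several places numbered 2357429 in replicate 1 and 1958627 in replicate 2, 0.910 and 0.855 for each read counted in a gene. Opposite-strand reads at genes with no opposite-strand miRNA neighbour numbered 396 and 191 in sum over all such genes, which had 2190320 and 2038951 own-strand counts. Of these, 330 and 142 lay at Mir203 (chromosome 12, 112130880 to 112130955), above the 3 that a count of 0 allows at a single gene, beside 2972 and 3706 own-strand counts.

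Within the let-7 family, the copies that share a mature sequence with another locus had low counts: Mirlet7a-1, Mirlet7a-2, Mirlet7c-1, Mirlet7c-2, Mirlet7f-1 and Mirlet7f-2 reached at most 3608 CPM, and the other 6 members at least 4616 CPM. A first test grouped the members by 18 bases shared with another miRNA gene, which took in 9 of 12, Mirlet7b among them, and the difference in mean log2(CPM + 1) was -1.96 (exact permutation p = 0.391, two-sided). A second grouping, by the fixed list of mature sequences with several loci (20 shared bases give the same split), was chosen after that outcome with the values in view, and it gave -5.39 (exact permutation p = 0.00216, the smallest that a split into 6 and 6 can give). An added condition, that the 34 detected members of that list outside the let-7 family lie below percentile 2.5 of random lists, was set after all 40 had been seen to lie at 6.99, and it was met narrowly at 2.38. Full-length reads of a mature sequence shared with another locus align to several places, and such reads are not in the gene counts. The low counts of these 6 genes are therefore no measure of the level of their miRNAs. The second grouping follows the pattern it was meant to test, so neither test decides how many reads were lost from these genes. Low transcription of those loci was not tested.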

How the results depend on the processing

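Leaving out genes that share 18 bases and asking for a 2-fold difference were chosen after seeing the data. The cause was not tested for any change below unless the setting itself gives it. A minimum of 1 count in place of 10 raised the miRNAs detected in both libraries from 339 to 560 by construction, and a minimum of 50 lowered them to 251. With strand ignored, 311 were detected. The share of the 10 most abundant miRNAs was 58.6% with strand ignored and 52.5% for the next 10 with Mirlet7b left out of the total, against 54.9%. Asking for a 2-fold difference as well left 65 of the 230 differing miRNAs. DESeq2's median gene-wise dispersion gave a coefficient of variation of 0.201 against 0.431, and on simulated counts it also lay below the true value. At a simulated 0.4 it returned 0.259. All genes were simulated with the same spread, so this does not decide between 0.201 and 0.431. Lists outside the central 95% fell from 5 to 3 with a minimum summed count of 200 and to 3 without the genes that share 18 bases, and the mesenchymal list crossed to percentiles 66.8 and 59.8, while the epithelial list could not be placed at 200 for lack of members. Of the other values for single lists and genes, leaving out a replicate aside, 327 kept their side or moved by less than the SD. Another 36 moved by more, all of these with strand ignored, 5 came to pass a threshold and 4 no longer passed. With strand ignored the counted reads fell from 2590051 to 2190727 in replicate 1 and from 2291030 to 2039157 in replicate 2. By construction this raised the CPM of genes that lost no reads, such as Mirlet7g, while overlapped genes such as Mir378a lost theirs. The number of differing miRNAs was 226 with DESeq2 size factors (93 higher in replicate 2), 226 with total counts, 228 with no filter and 211 with strand ignored. Leaving out either replicate gave 362 to 366 detected miRNAs and a neighbour correlation of 0.317 to 0.365. The share of the 10 most abundant was then 56.2% to 56.4%, with the 10 ranked anew within the library that was left. Replicate 1 alone thus gave 56.4%, against 53.7% for the 10 ranked over both libraries. With 2 libraries, leaving 1 out always moves a mean by less than the SD, so the 160 such values say nothing of stability, and the striated muscle list went from 339 CPM to 81.2 or 598. Depth limits miRNAs near 20 summed counts, and with 2 libraries no spread beyond these samples can be given.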

Other observations

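The tests of counting noise and of muscle RNA below, and the shuffling of directions within clusters, were chosen after the result was seen.

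The 6 miRNA genes of the Hox clusters held 5.64% ± 0.935 of counts (SD, n = 2), with 129072 counts in replicate 1 and 144480 in replicate 2. Mir10a and Mir10b gave most of this, and Mir615, in an intron of Hoxc5 and named after its values were seen, reached 2174 ± 547 CPM (SD, n = 2). By host, 36.9% ± 1.93 of counts came from miRNAs in introns of protein-coding genes, 11.4% ± 3.66 from miRNAs overlapping their exons and 26.4% ± 1.18 from intergenic miRNAs (SD, n = 2 each). Chromosome X gave 4.18% ± 0.204 (SD, n = 2). The Mir23 pair held 7.57% ± 3.87, with 125245 and 236204 counts, while the Mir27 and Mir24 genes of the same clusters held 0.511% ± 0.169, with 16325 and 8961 counts (SD, n = 2 each). The Mir24 genes are on the list of mature sequences with several loci, and reads that align to several places are not counted. All of the Mir23, Mir27 and Mir24 genes share 18 bases with another miRNA gene. The gap between these shares is therefore no measure of a difference in level.

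Reads of 62.7% of the tested miRNAs differed between the libraries in a test with counting error as its only spread, which restates the pattern and does not weigh its cause. A linear fit on the base composition of the annotated hairpin removed 0.725% of the variance of the log2 ratios (Spearman 0.166, permutation p = 0.00141). This is too little to account for the spread of the ratios as a whole. Their SD was 1.14, and single large ratios, such as -8.75 for Mir208a, weigh heavily in the variance. The fit therefore does not decide whether composition bears on the many smaller differences. Composition of the reads themselves was not tested. If transcription of shared primary transcripts were the whole cause, neighbours would move together, and their median difference lay at percentile 4.38 of matched random pairs within 10 kb, between the bounds of 2.5 and 10 set for that distance, but at 14.1 within 2 kb and 13.8 without genes that share 18 bases, both above them, and at 3.88 within 50 kb, so this cannot be told apart. Clusters with members in both directions numbered 11, fewer than the 19 (95% range 14 to 24) obtained by shuffling directions (permutation p = 0.00230), yet Mir23a and Mir27a moved apart. A difference between the tissue samples stays open and untested.

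The striated muscle miRNAs stood higher in replicate 1, and 4 of 4 members with at least 10 counts passed the exact test; the pattern was noticed from the same 4, so this is no separate test of it. Muscle RNA or reads in replicate 1 are a candidate source, from a list of 9 fixed with the others, 1 of them with 10 counts in both libraries, but the Mir1a and Mir133 genes, the most abundant miRNAs of muscle, summed to only 1.16 CPM there. All 5 of those genes share 18 bases with another miRNA gene, so their reads may be lost among those that align to several places, and the source cannot be told apart. Mir208a, Mir208b and Mir499 together held 312 CPM in replicate 1 and 1.75 CPM in replicate 2. The labels give 1 group, so no biological explanation drawn from the design could be set against this.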
